A study of Arabidopsis thaliana with 12 samples.

How the data were processed

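Gene expression was measured with Affymetrix ATH1 arrays in 14-day-old Arabidopsis seedlings of wild type and the rcf1-1 mutant after 0 h, 12 h and 24 h at 4 °C. The 12 arrays form 6 groups of 2 biological replicates, taken from the labels. The values used are the deposited log2 values, 1 per probe set and array, made with RMA per the submitters' processing notes. The RMA software, its version and the set of arrays normalized together are not given in the sources used here. Scanner files were not used here.

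The table holds 22810 probe sets. The 64 control probe sets were left out of the tests and kept for array quality, which left 22746. Probe sets were named through the array's probe annotation and the gene table of assembly TAIR10.1. That annotation gave exactly 1 gene for 13513 probe sets, several genes for 503 and none for 8730. The named probe sets cover 13350 genes, of which 1594 have a symbol other than the locus number. Probe sets without a gene were tested and counted but not named. Names ending in _x_at or _s_at mark probe sets that can also bind transcripts of related genes. The number of arrays limits the precision of every value.

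Tests used limma 3.58.1 in R 4.3.3. A mean was fitted per group with lmFit on all 12 arrays, which left 6 residual degrees of freedom. Variances were moderated with eBayes and a trend on mean expression (prior degrees of freedom 4.7). The 10 contrasts were rcf1-1 against wild type at each time and averaged over the 3 times, each genotype at 12 h and 24 h against 0 h, and the differences between the genotypes' cold responses at 12 h and 24 h. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all probe sets within a contrast. A probe set was called at an adjusted p under 0.05. Errors of log2 differences are limma's standard errors, which pool the spread over all groups. Overlaps of called probe sets were tested with Fisher's exact test.

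Gene lists were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. The 16 fixed lists were CBF regulators, COR genes, splicing factors of the SR family, circadian clock, heat shock, flavonoid and anthocyanin, abscisic acid and drought, photosynthesis, salicylic acid and defence, jasmonate, ribosome biogenesis, starch and soluble sugars, oxidative and mitochondrial stress, leaf senescence, root markers, and stomatal lineage and guard cell markers. Of their 317 genes, 48 were paired with a probe set. A list was tested when at least 3 of its genes were paired, which held for 9. Each gene was taken from its probe set with the highest mean. A further 17 lists were drawn from the annotation's symbols after the data had been seen, and the results given for them stand with the other observations.

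The contrasts, the threshold, the fixed lists, most of the other settings and the rule for naming genes were set before the data were examined. The rule names, per genotype contrast and per wild-type cold contrast, the 10 called probe sets with the largest log2 difference in each direction, if they have exactly 1 gene and the 2 arrays of each group lie apart. Where fewer than 10 were called, those with the smallest p follow. It names the 3 largest called members of each list, and the 5 largest in each direction for the other contrasts. Of 19 genes that were to be named in any case, 3 were paired with a probe set. The others, among them RCF1, CBF1, CBF2, CBF3, RD29A and KIN1, are not analysed here.

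The other settings chosen in advance were a fit without the trend, a filter removing probe sets below the 30th percentile of the mean, a second quantile normalization, a replicate block, array quality weights, the arrays of the compared groups alone, a minimum change of 2-fold, and leaving out each array in turn. Lists were also tested with the mean over all probe sets of a gene, and overlaps at an adjusted p under 0.01. A fit without both 24 h replicate 2 arrays, and a fit with a term for those arrays, were chosen after seeing the data.

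The procedure was tested on simulated data with 22746 probe sets, of which 200 were changed in each of 5 simulations. The spread of each group was taken from the data, with the shift that both 24 h replicate 2 arrays share. For rcf1-1 against wild type at 0 h, 95.6% of 8-fold, 88% of 4-fold, 28% of 2-fold and 6.8% of 1.5-fold changes were called, and 0.183% of the calls were false. For the same contrast at 24 h the shares were 98%, 82%, 31.6% and 10.8%, with 2.8% of the calls false. A first simulation gave the 24 h arrays the same spread with no shared shift. In it, 82.5% of the calls for rcf1-1 against wild type at 24 h were false, or 629.8 per simulation. The false share for wild type at 24 h against 0 h was 5.05% with the shared shift and 32.2% without it. The calls at 24 h therefore rest on the shift being shared, for which the measured correlation is given with the arrays. These false shares hold for 200 changed probe sets and depend on that number. A list shifted by 1 log2 unit was called in 5 of 5 simulations for rcf1-1 against wild type at 0 h.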

Results

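Transcript levels were measured in whole seedlings of wild type and the rcf1-1 mutant, which carries a lesion in a DEAD-box RNA helicase gene. The wild type was Columbia gl1 with a CBF2::LUC reporter. Seedlings were grown at 21 °C and moved to 4 °C for 12 h or 24 h, and those at 0 h were not chilled. Each of the 6 groups had 2 arrays, and values are log2 RMA values. A group mean below the median of every array is treated here as close to the lowest signals, and a difference from such a group as a lower bound in size. This is a convention, and some probe sets read lower still in another group. Replicate arrays correlated across probe sets at r from 0.989 to 0.996 at 0 h and 12 h. At 24 h the correlation was 0.955 in wild type and 0.954 in rcf1-1.

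The first principal component, with 45.5% of the variance, separated chilled from unchilled seedlings. On it the rcf1-1 arrays at 24 h scored 54.3 and 57.3, against 10.8 and 22 for wild type. The second, with 22.1%, set the 24 h replicate 2 arrays of both genotypes apart, at 79.3 in wild type and 60.7 in rcf1-1. On these 2 arrays the actin control had 5' minus 3' log2 differences of -6.15 and -5.89, against -2.03 to -1.49 on the other 10. The GAPDH control gave -5.13 and -4.45, against -1.06 to -0.29. The replicate differences of both genotypes at 24 h correlated at r = 0.69 across probe sets, so that much of this spread cancels between genotypes. COR15A, a cold-regulated chloroplast protein gene, moved with it, from 12.67 in replicate 1 to 11.13 in replicate 2 in wild type and from 12.57 to 11 in rcf1-1.

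**Figure D1:**
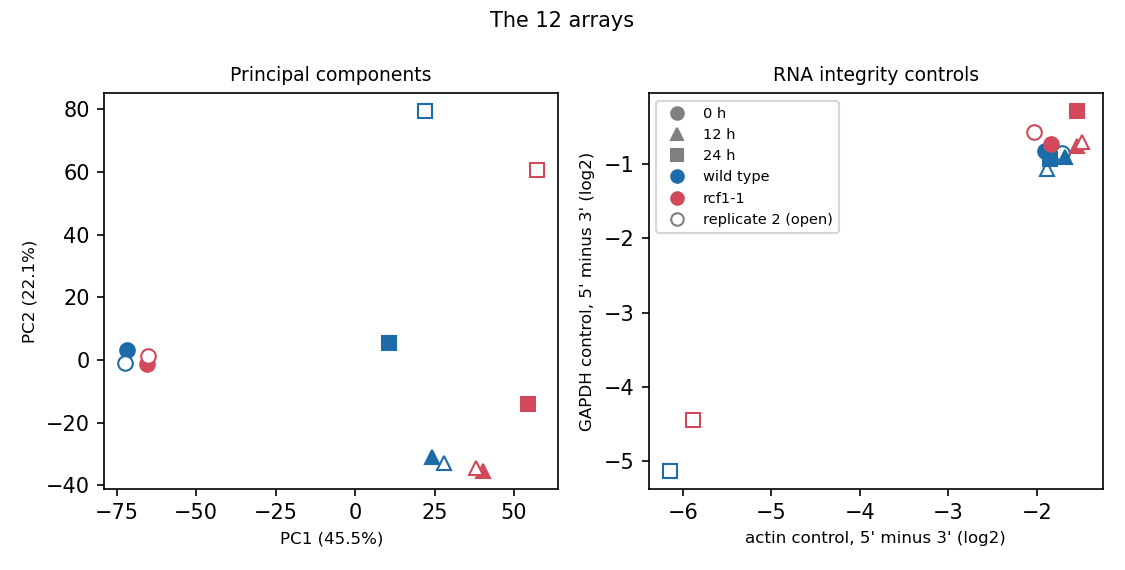
The 12 arrays on the first 2 principal components (left; scores, with the percent of variance) and by the 5' minus 3' log2 differences of the actin and GAPDH controls (right). Colour marks the genotype, shape the hours at 4 °C and open symbols replicate 2. The 24 h replicate 2 arrays of both genotypes lie apart in both plots, with actin differences of -6.15 and -5.89.

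The effect of the mutation without cold was measured by comparing rcf1-1 with wild type at 0 h. UPOX, a mitochondrial gene known for its rise under oxidative stress, was higher by 3.81 ± 0.27 on the log2 scale (SE, n = 2 per genotype; adjusted p = 0.00076). The plant defensin genes PDF1.2 and PDF1.2b were higher by 4.39 ± 0.49 (adjusted p = 0.0097) and 4.66 ± 0.7 (adjusted p = 0.042). The PDF1.2b probe set, an _x_at set, can also bind related defensin transcripts. AT4G33720 was higher by 4.96 ± 0.53. JAL23 was higher by 4.06 ± 0.45, and BHLH101, a transcription factor gene of the iron deficiency response, by 3.16 ± 0.33. These 6 differences are treated as lower bounds, with wild-type means of 2.99 for AT4G33720 to 3.86 for BHLH101. In wild type BHLH101 read lower still at 12 h (2.46) and 24 h (2.71), so its 0 h value was not at its lowest signal. The called genes with lower values were AT5G22460 at -1.71 ± 0.23, AT2G41190 at -1.51 ± 0.21 and AT5G45310 at -1.35 ± 0.2, the last a lower bound in size with 3.11 in rcf1-1. COR15A, at 3.91 in rcf1-1, differed by -1.35 ± 0.51 (adjusted p = 0.6), and COR47, a dehydrin gene, by -0.32 ± 0.2 (adjusted p = 0.92). COR15A differed by -1.49 to -1.21 whichever 0 h array was left out. Its standard error pools all groups, among them those at 24 h, where its replicates lay far apart. The missing call therefore does not show equal levels. The uncalled named values at 0 h include COR15A and COR47. Of those values, 8 were called with array quality weights and 8 with the compared arrays alone. AT3G09620, the gene of the related helicase RH45, had values of 2.7 to 2.89 in the 6 groups, below the array medians, so a difference could not be measured for it.

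In all, 25 probe sets were called at 0 h, 21 of them higher and 4 lower in rcf1-1. With the compared arrays alone 331 were called, 201 higher and 130 lower, and with array quality weights 995, 621 higher and 374 lower. The values that follow are from the reported fit unless another is named. Of the 3 paired jasmonate genes, 2 were called higher and 3 were higher when adjusted over the list alone (camera adjusted p = 3.65e-10, and 0.0222 with an estimated correlation). They are PDF1.2, PDF1.2b and THI2.1, and none of the list's JAZ, LOX or AOC genes was paired. As the PDF1.2b probe set can bind related defensin transcripts, PDF1.2 and PDF1.2b may not be separate signals. The list p counts them as 2 genes at every time. The 8 paired ribosome biogenesis genes had a median of 0.64 (adjusted p = 8.17e-09, and 0.0222 with an estimated correlation). None of them was called on its own over all probe sets, and 5 were higher when adjusted over the list alone. The flavonoid list had a median of 0.73 over 5 genes (adjusted p = 0.002), with 0 called either way, and adjusted p = 0.178 with an estimated correlation. The oxidative and mitochondrial stress list, in which UPOX was the only called member of 3, gave 0.00227, and adjusted p = 0.0744 with an estimated correlation. Adjusted over the list alone, 1 of its genes was higher. Leaving out 1 array gave 4 calls without wild-type replicate 1, 2 without wild-type replicate 2, 18 without rcf1-1 replicate 1 and 4 without rcf1-1 replicate 2. Of the 13 called genes under the naming rule, UPOX alone was called in all 4 of these fits.

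The effect of the mutation in the cold was measured by comparing the genotypes at 12 h and 24 h. At 12 h, AT4G33720 was higher in rcf1-1 by 5.27 ± 0.53 (SE, n = 2 per genotype; adjusted p = 0.0013), PDF1.2 by 5.19 ± 0.49 and UPOX by 4.15 ± 0.27 (adjusted p = 4.5e-05). AT2G41730, measured by an _x_at probe set that can bind related transcripts, was higher by 4.99 ± 0.27. AT2G32020 was higher by 4.85 ± 0.34 and AT2G04050 by 4.43 ± 0.28. BZIP60, a transcription factor gene of the unfolded protein response that was named after its values were seen, was higher by 1.51 ± 0.21 (adjusted p = 0.0085). AT4G01130 was lower at -2.99 ± 0.25, AT1G53430 at -2.97 ± 0.32 and AT1G07650 at -2.43 ± 0.29. The sterol glucosyltransferase gene UGT80B1 was lower at -2.28 ± 0.26. The differences of AT4G33720, PDF1.2, UPOX and AT2G04050, with wild-type means of 2.85 to 3.51, and of AT4G01130, AT1G53430 and AT1G07650, with rcf1-1 means of 3.24 to 3.93, are lower bounds in size. COR15A differed by -0.07 ± 0.51 and COR47 by 0.06 ± 0.2, neither of them called. With group means of 12.43 to 12.99 at 12 h, both lay close to the array maxima of 12.77 to 13.38, where a difference is hard to detect.

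The 12 h contrast called 307 probe sets, 123 higher and 184 lower in rcf1-1. Array quality weights gave 2982, the compared arrays alone 3874 and a fit without the trend 478, each with more lower than higher. The list results here are from the reported fit. All 3 paired jasmonate genes (PDF1.2, PDF1.2b and THI2.1) were higher, also when adjusted over the list alone (adjusted p = 2.82e-08, and 0.0402 with an estimated correlation). The oxidative and mitochondrial stress list had a median of 1.65, with 1 of 3 genes called and 2 adjusted over the list alone (adjusted p = 1.18e-04, and 0.0402 with an estimated correlation). The flavonoid list had a median of 0.93, with 0 of 5 genes called and 3 higher adjusted over the list alone (adjusted p = 0.0078, and adjusted p = 0.405 with an estimated correlation). Leaving out 1 array gave 37 calls without wild-type replicate 1, 40 without wild-type replicate 2, 23 without rcf1-1 replicate 1 and 39 without rcf1-1 replicate 2, and in each of these 4 fits more were higher than lower (24 and 13, 24 and 16, 18 and 5, 25 and 14). AT4G33720, PDF1.2, UPOX, AT2G41730, AT2G32020, AT2G04050, AT4G01130 and AT1G53430 were called in all 4 of these fits, while PDF1.2b, THI2.1, BZIP60, AT1G07650 and UGT80B1 were not.

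At 24 h, AT2G41730 was higher in rcf1-1 by 7.72 ± 0.27 (SE, n = 2 per genotype; adjusted p = 2.8e-07), AT2G04050 by 7.34 ± 0.28 and UPOX by 6.58 ± 0.27. NDB4, a gene for an alternative NAD(P)H dehydrogenase of mitochondria, was higher by 4.88 ± 0.25 (adjusted p = 3.1e-06). HSP23.5, a mitochondrial small heat shock protein gene, was higher by 4.46 ± 0.48, and PDF1.2 by 4.5 ± 0.49. With wild-type means of 3.12 to 3.78, the differences of AT2G04050, UPOX, NDB4 and PDF1.2 are lower bounds. BZIP60 was higher by 3.19 ± 0.21 and the autophagy gene ATG8E by 3.04 ± 0.28, both named after their values were seen. Lower genes included AT1G73600 at -2.67 ± 0.59, AT5G59950 at -2.54 ± 0.49, AT3G62040 at -2.44 ± 0.44 and AT1G49750 at -2.37 ± 0.26. The ribosome biogenesis genes WDR12 (-1.15 ± 0.23), BOP1 (-0.96 ± 0.18) and PES (-0.87 ± 0.2) were also lower. STZ, a zinc finger gene and the only CBF regulator paired with a probe set, was higher by 1.85 ± 0.29, and was called over all probe sets. As it is the only paired gene of its list, adjustment over the list alone leaves its p as it is. By an unadjusted p under 0.05 STZ was also higher at 0 h, by 1.59 ± 0.29, and at 12 h, by 0.83 ± 0.29. At these times it was not called over all probe sets.

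The 24 h contrast called 1706 probe sets, 753 higher and 953 lower. Of the 8 ribosome biogenesis genes, 3 were lower over all probe sets and 4 adjusted over the list alone (adjusted p = 0.00368, and adjusted p = 0.179 with an estimated correlation). The jasmonate list kept a median of 4.39, with 3 of 3 higher both ways (adjusted p = 3.94e-05, and adjusted p = 0.107 with an estimated correlation). The oxidative and mitochondrial stress list had 2 of 3 genes higher both ways (adjusted p = 2.09e-04, and adjusted p = 0.0925 with an estimated correlation). Among 7 COR genes, COR27 alone was called, at 1.67 ± 0.37, and 4 were higher adjusted over the list alone (adjusted p = 0.00105, and adjusted p = 0.246 with an estimated correlation). COR15A differed by -0.12 ± 0.51 and COR47 by 0.46 ± 0.2, neither called, at group means of 11.78 to 12.72. For COR15A, replicate 1 was close to the array maxima in both genotypes, while replicate 2 lay well below them. With a term for both 24 h replicate 2 arrays, 1 of COR15A, COR47 and AT3G09620 was called. Of the 4 heat shock genes, HSP23.5 alone was called, also adjusted over the list alone (adjusted p = 0.00795, and adjusted p = 0.246 with an estimated correlation). The flavonoid list, with a median of 0.1 and a mean of -0.22, gave a camera adjusted p of 0.621. Of its 5 genes UGT78D1 alone was called, lower at -1.62 ± 0.34 (-1.07 without wild-type replicate 1, and adjusted p = 0.054 without rcf1-1 replicate 2), and 1 was higher and 1 lower adjusted over the list alone. Leaving out rcf1-1 replicate 2 raised the count to 2917, while leaving out any other 24 h array gave between 1768 and 2269. More were higher than lower without rcf1-1 replicate 2 (1644 and 1273), without rcf1-1 replicate 1 (918 and 850), after a second quantile normalization (964 and 945), with array quality weights (175 and 93) and with the compared arrays alone (17 and 0). With the compared arrays alone, 38 of the 49 named calls at 24 h were lost. Without their shared 24 h shift, 82.5% of simulated calls in this contrast were false. With a single 24 h array left out, the shift shared by both replicate 2 arrays no longer cancels between genotypes. The counts, directions and values from those fits therefore hold part of that shift, and similar counts do not show the same probe sets. Without rcf1-1 replicate 2, AT1G73600 was at -1.59 and AT5G59950 at -1.61, and AT1G73600 lost its call without wild-type replicate 1 (adjusted p = 0.074). PES lost it without replicate 1 of wild type (0.054) or of rcf1-1 (0.05), and COR27 without wild-type replicate 2 (0.076) or rcf1-1 replicate 1 (0.084).

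**Figure D2:**
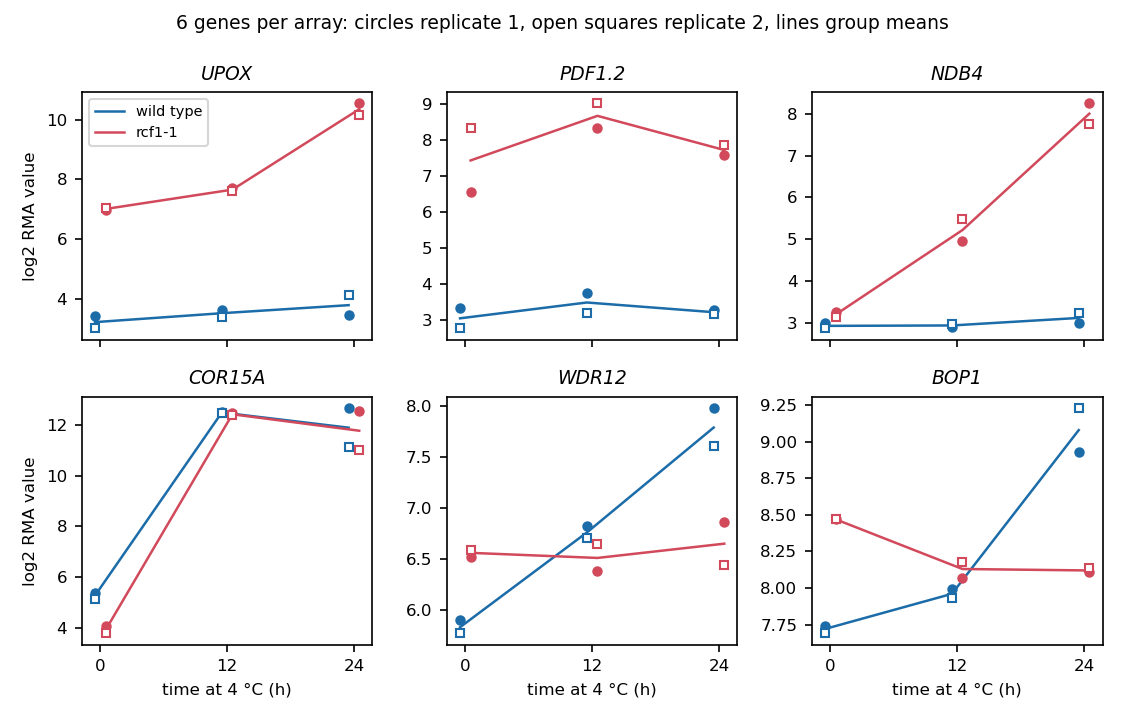
Log2 RMA values of 6 genes on each array against the hours at 4 °C. Filled circles are replicate 1, open squares replicate 2 and lines join group means (n = 2). UPOX was higher in rcf1-1 at every time, by 3.81, 4.15 and 6.58, while COR15A differed by -0.12 at 24 h.

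The genotype differences at the 3 times come from separate arrays but share a single spread estimate per probe set. A probe set with a small spread is called more easily at each time, and probe sets are not independent units. The expected overlaps and the p of Fisher's exact test take neither into account. Between 12 h and 24 h, 84 probe sets were higher in rcf1-1 at both times, where independent lists would share 4.07 (Fisher's exact test, adjusted p = 7.56e-95). A further 92 were lower at both, with 7.71 expected (adjusted p = 2.36e-76), and 0 were higher at 12 h and lower at 24 h. Those lower at 12 h and higher at 24 h were not counted. Between 0 h and 12 h, 13 higher probe sets were shared (0.114 expected), and between 0 h and 24 h 14 (0.695 expected). The single lower probe set shared by 0 h and 12 h stood against 0.0324 expected, and 0 were shared by 0 h and 24 h. Across probe sets, which are not independent replicates, the differences correlated at r = 0.53 between 12 h and 24 h, 0.42 between 0 h and 12 h, and 0.25 between 0 h and 24 h. At all 3 times 13 probe sets were called, each in the same direction, among them UPOX, PDF1.2, PDF1.2b, JAL23, AT4G33720 and JRG21. JRG21, which lies outside the naming rule and was chosen after its values were seen, was higher by 1.98, 2.45 and 1.93.

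Averaged over the 3 times, with 6 arrays per genotype, UPOX was higher by 4.85 ± 0.16 (adjusted p = 1.4e-07), PDF1.2b by 4.71 ± 0.4, PDF1.2 by 4.7 ± 0.28, AT4G33720 by 4.63 ± 0.3 and AT2G41730 by 4.62 ± 0.16. AT5G59130 was lower at -2.04 ± 0.2, AT1G53430 at -1.65 ± 0.18, AT1G07650 at -1.59 ± 0.16, AT5G20220 at -1.49 ± 0.16 and AT5G59950 at -1.49 ± 0.28. These 10 genes were called whichever single array was left out, and for all but AT5G20220 and AT5G59950 at least 1 group mean was close to the lowest signals. The averaged contrast called 1921 probe sets, 836 higher and 1085 lower. At a minimum of 2-fold 231 were higher and 118 lower, and without rcf1-1 24 h replicate 2 there were 1684 and 1565. The jasmonate list had 3 of 3 genes higher both ways (adjusted p = 1.25e-07, and 0.0443 with an estimated correlation), and the oxidative and mitochondrial stress list 2 of 3 both ways (adjusted p = 1.46e-04, and 0.0443 with an estimated correlation). The heat shock list had 1 of 4 genes higher both ways (adjusted p = 0.011, and adjusted p = 0.332 with an estimated correlation). Of the 4 stomatal lineage and guard cell markers, GC1 alone, named after its values were seen, was called, at -0.62 ± 0.12, and 2 were lower adjusted over the list alone (adjusted p = 0.0888). The count lay between 804 and 1271 without any 1 of the 0 h or 12 h arrays and between 2184 and 3249 without any 1 of the 24 h arrays.

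The wild-type response to cold was measured against 0 h. At 12 h, COR15B rose by 8 ± 0.18 (SE, n = 2 per time; adjusted p = 3.3e-09), COR15A by 7.24 ± 0.51, COR27 by 7.51 ± 0.37 and COR47 by 3.78 ± 0.2. AT5G62360 rose by 7.91 ± 0.35 and AT1G51090 by 7.56 ± 0.3. The clock gene GI, the only paired member of its list, rose by 4.67 ± 0.3, STZ by 4.14 ± 0.29, and LEA4-5, the only paired abscisic acid and drought gene, by 4.2 ± 0.72. The expansin gene EXPA8 fell by 5.42 ± 0.22 and AT2G34620 by 4.66 ± 0.25. GI, STZ and LEA4-5 were each called over all probe sets. Each is the only paired gene of its list, so adjustment over the list alone leaves its p as it is. The rises of COR15B, COR27, AT5G62360, AT1G51090 and STZ, from 0 h means of 2.43 to 3.72, and the fall of EXPA8, to 3.56, are lower bounds. So are the rises of COR15A and COR47, whose 12 h means are close to the array maxima (12.5 for COR15A). At 24 h, COR15B rose by 7.79 ± 0.18, COR15A by 6.64 ± 0.51, AT4G30650 by 6.31 ± 0.25 and the dehydrin gene LTI30 by 4.29 ± 0.3. AT4G27450 fell by 6.05 ± 0.3, EXPA8 by 4.38 ± 0.22 and LHCB4.2, an antenna protein gene of photosystem II, by 2.51 ± 0.26. At 24 h the rise of COR15B, from 3.4, and the fall of AT4G27450, to 3.66, are lower bounds. WDR12 rose by 1.96 ± 0.23, and BRX1-1, another ribosome biogenesis gene, by 2.11 ± 0.23.

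At 12 h, 2724 probe sets were called in wild type, 1377 up and 1347 down, and at 24 h 2994, with 1326 up and 1668 down. More fell than rose at 12 h with array quality weights (2403 up, 2829 down), the compared arrays alone (2341 and 2662), the dim filter (1466 and 1514) and no trend (1458 and 1526), and more rose than fell at 24 h without wild-type 24 h replicate 2 (1360 and 1136). All 7 paired COR genes rose at 12 h, also adjusted over the list alone (adjusted p = 1.15e-17, and adjusted p = 0.0709 with an estimated correlation). At 24 h 6 of them rose over all probe sets and 7 adjusted over the list alone (adjusted p = 5.34e-12, and adjusted p = 0.084 with an estimated correlation). Of the 8 ribosome biogenesis genes, 4 rose at 12 h both ways (adjusted p = 2.73e-04, and adjusted p = 0.116 with an estimated correlation). At 24 h 6 rose over all probe sets and 7 adjusted over the list alone, with a median of 1.57 (adjusted p = 5.3e-08, and adjusted p = 0.0515 with an estimated correlation). Of 3 photosynthesis genes, LHCB4.2 alone fell at 24 h over all probe sets and 3 fell adjusted over the list alone (adjusted p = 0.00765, and adjusted p = 0.267 with an estimated correlation). In the oxidative and mitochondrial stress list, GSTU25 alone rose at 24 h (adjusted p = 0.00018), and 1 gene adjusted over the list alone (adjusted p = 0.0347, and adjusted p = 0.213 with an estimated correlation). Of the 2 paired leaf senescence genes, WRKY6 rose at 12 h by 1.56 ± 0.32 and SAG29 fell at 24 h by 2.73 ± 0.47. WRKY6 lost its call without 0 h replicate 1 (adjusted p = 0.086) or 12 h replicate 2 (0.098). Adjusted over the list alone, 1 of these 2 rose at 12 h, and 1 rose and 1 fell at 24 h. No unchilled seedlings of the later times are among the samples, so time of day and age move with the cold. The 24 h count was 5575 without wild-type 24 h replicate 1, 2496 without replicate 2, and 1750 or 1415 without 0 h replicate 1 or replicate 2. The 12 h count was 1620 and 1474 without each 0 h array, and 1434 and 1267 without each 12 h array.

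In rcf1-1 at 12 h, COR15A rose by 8.52 ± 0.51 (SE, n = 2 per time; adjusted p = 2.2e-06), COR15B by 8.33 ± 0.18, COR47 by 4.16 ± 0.2 and COR27 by 7.51 ± 0.37, while EXPA8 fell by 5.54 ± 0.22. At 24 h, COR15B rose by 8.19 ± 0.18, COR15A by 7.87 ± 0.51, AT2G41730 by 7.33 ± 0.27 and AT2G04050 by 6.76 ± 0.28. EXPA8 fell by 5.13 ± 0.22 and AT1G47400 by 4.84 ± 0.95. The rises of COR15A, COR15B, COR27 and AT2G04050, from 0 h means of 2.38 to 3.91, and the falls of EXPA8 and AT1G47400, to means of 3.13 to 3.99, are lower bounds. So is the 12 h rise of COR47, whose 12 h mean is close to the array maxima. All 7 COR genes rose at both times, over all probe sets and adjusted over the list alone (adjusted p = 3.3e-17 at 12 h, and adjusted p = 0.0754 with an estimated correlation; 1.05e-11 at 24 h, and adjusted p = 0.0885 with an estimated correlation). At 24 h, 3 of the 5 flavonoid genes fell, and 4 adjusted over the list alone (adjusted p = 0.0315, and adjusted p = 0.47 with an estimated correlation). Of the 3 photosynthesis genes, 2 fell both ways (adjusted p = 0.0244, and adjusted p = 0.47 with an estimated correlation). The oxidative and mitochondrial stress list had 1 riser at 12 h, and 3 adjusted over the list alone (adjusted p = 0.0134, and adjusted p = 0.163 with an estimated correlation). At 24 h it had 2, and 3 adjusted over the list alone (adjusted p = 0.00111, and adjusted p = 0.0885 with an estimated correlation). Of the 8 ribosome biogenesis genes, 0 were called at 12 h and 2 rose at 24 h, by either adjustment (camera adjusted p = 0.365 and 0.282).

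The contrasts in rcf1-1 called 2784 probe sets at 12 h, 1242 up and 1542 down, and 4734 at 24 h, 1906 up and 2828 down. At 12 h, 885 risers and 892 fallers were shared with wild type, where independent lists would share 75.2 and 91.3. Of the wild-type risers 3 fell in rcf1-1, and wild-type fallers that rose in rcf1-1 were not counted. At 24 h, 714 and 1159 were shared, with 111 and 207 expected. Of the wild-type risers 15 fell in rcf1-1, and the reverse was again not counted. The expected overlaps here also leave out the spread estimate that the contrasts share. The responses of the genotypes, which share no array, correlated across probe sets at r = 0.86 at 12 h and 0.73 at 24 h. Leaving out 1 array gave 1352 and 1384 calls at 12 h without each 0 h array, and 1335 and 1430 without each 12 h array. More rose than fell at 12 h without 0 h replicate 2 (697 and 687), 12 h replicate 1 (681 and 654) or 12 h replicate 2 (721 and 709). At 24 h it gave 2078 and 2126 without each 0 h array, and 6828 and 4399 without 24 h replicate 1 and replicate 2.

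**Figure D3:**
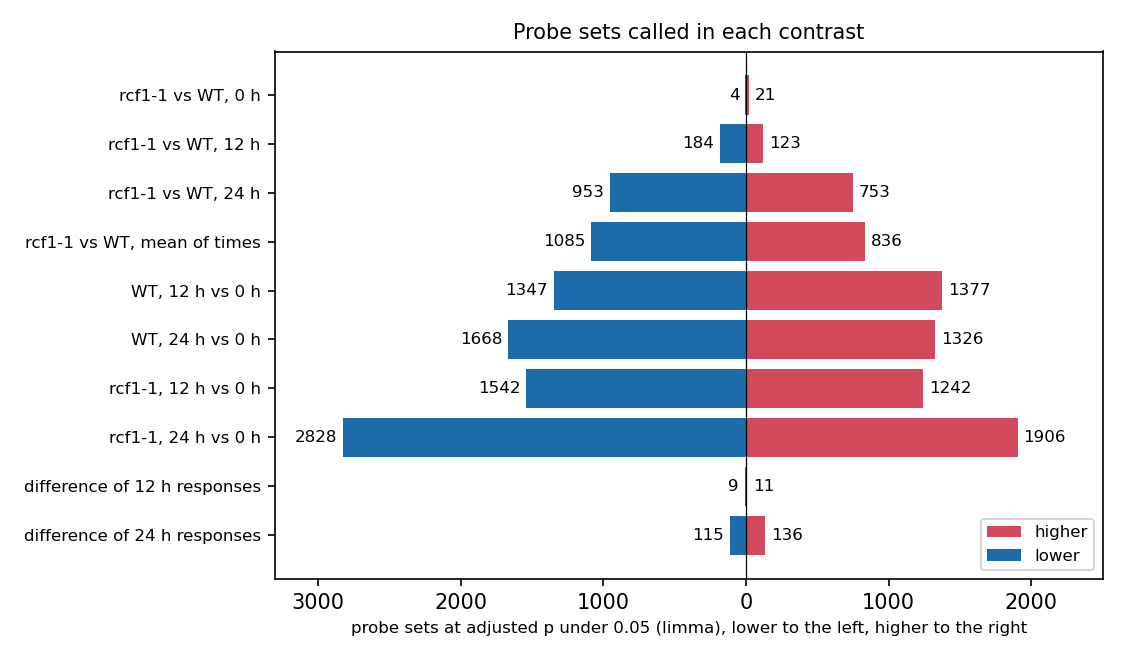
Probe sets called at an adjusted p under 0.05 in each of the 10 contrasts (horizontal axis, number of probe sets), with lower ones drawn to the left and higher ones to the right. The difference between the genotypes was called for 25 probe sets at 0 h, 307 at 12 h and 1706 at 24 h.

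Whether the mutation altered the cold response was tested directly as the difference between the genotypes' changes from 0 h. At 24 h the response was larger in rcf1-1 by 6.55 ± 0.38 for AT2G41730 (SE, n = 2 per group; adjusted p = 2.9e-05), 6.49 ± 0.4 for AT2G04050, 4.98 ± 0.47 for AT2G32020 and 4.61 ± 0.35 for NDB4. It was lower at -3.13 ± 0.47 for BHLH101, -2.71 ± 0.44 for AT2G03420 and -2.53 ± 0.29 for AT3G18600. BHLH101 was close to the lowest signals at 24 h in both genotypes (2.71 and 2.74), so its value is the difference at 0 h and no measure of its cold response. AT2G41730, AT2G04050, AT2G32020 and NDB4 had 0 h means of 3.31, 2.89, 3.67 and 2.93 in wild type, also close to the lowest signals. The ribosome biogenesis genes WDR12, BOP1 and PES, chosen here after their values were seen, had differences of -1.87 ± 0.32 (adjusted p = 0.022), -1.71 ± 0.26 (adjusted p = 0.013) and -1.46 ± 0.28 (adjusted p = 0.034). Without rcf1-1 0 h replicate 1, rcf1-1 0 h replicate 2 or wild-type 0 h replicate 2, all 3 lost their call (WDR12 adjusted p = 0.13, 0.15 and 0.12; BOP1 0.097, 0.1 and 0.07; PES 0.19, 0.19 and 0.16). Without wild-type 0 h replicate 1, WDR12 (0.065) and PES (0.057) did. WDR12 rose by 1.96 in wild type and differed by 0.09 from 0 h in rcf1-1, which was not called. For WDR12, BOP1 and PES, part of the difference in response is a higher level in rcf1-1 at 0 h. That 0 h difference was not called for any of them. At 12 h the response was larger in rcf1-1 by 4.75 ± 0.47 for AT2G32020 (adjusted p = 0.0035) and 3.13 ± 0.27 for AT5G15950. It was lower at -2.98 ± 0.37 for AT4G21870 and -2.92 ± 0.35 for AT4G01130. COR15A gave 1.28 ± 0.72 at 12 h and 1.23 ± 0.72 at 24 h, neither called. Of COR15A, COR47 and AT3G09620, all uncalled, 1 was called at 12 h with array quality weights and with the compared arrays alone. At 24 h 2 of them were called with a term for both 24 h replicate 2 arrays. The 12 h values of COR15A lie close to the array maxima. As it differed little between the genotypes in the cold, its values here are mostly its difference at 0 h (5.27 in wild type, 3.91 in rcf1-1).

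The difference of the responses was called for 20 probe sets at 12 h, 11 positive and 9 negative, and for 251 at 24 h, 136 positive and 115 negative. More were negative than positive at 12 h with array quality weights (205 positive, 379 negative) and the compared arrays alone (250 and 435), and at 24 h without the trend (203 and 264), with the dim filter (170 and 189) and without wild-type 24 h replicate 2 (198 and 350). Without rcf1-1 0 h replicate 2 there were 34 and 3 at 24 h. The ribosome biogenesis list had medians of -0.47 at 12 h (adjusted p = 3.42e-04, and adjusted p = 0.208 with an estimated correlation) and -1.15 at 24 h (adjusted p = 1.48e-07, and adjusted p = 0.054 with an estimated correlation). Between genotypes this list was not called at 12 h (median 0.15, adjusted p = 0.627), and the value for 12 h comes mostly from its higher level in rcf1-1 at 0 h (median 0.64). That higher 0 h level is part of the 24 h value too. Of its 8 genes, 0 were called at 12 h by either adjustment, and at 24 h 3 were negative over all probe sets and 5 adjusted over the list alone. The COR genes had a median of 0.95 at 24 h, with 0 of 7 called and 1 adjusted over the list alone (adjusted p = 3.52e-04, and adjusted p = 0.391 with an estimated correlation). The oxidative and mitochondrial stress list had 1.76, with 1 of 3 called and 2 adjusted over the list alone (adjusted p = 0.00185, and adjusted p = 0.0952 with an estimated correlation). Each of the 8 arrays left out in turn lowered the 12 h count, to between 4 and 9. For 24 h the count was 123, 51, 44 and 37 without each 0 h array of wild type and then of rcf1-1, and 438, 548, 400 and 964 without each 24 h array.

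**Figure D4:**
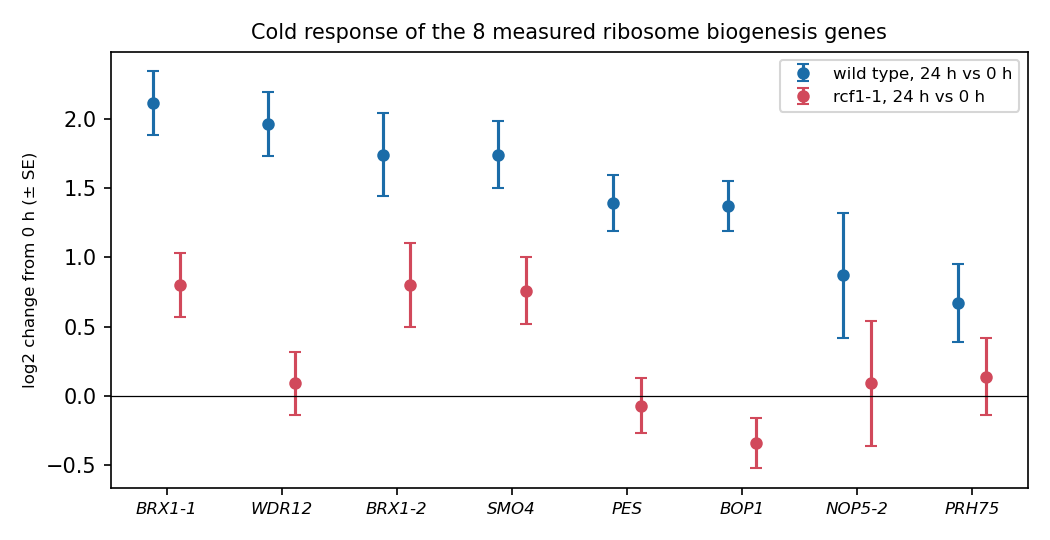
Log2 change from 0 h to 24 h at 4 °C of the 8 paired ribosome biogenesis genes, with limma's standard errors (n = 2 arrays per group and time). WDR12 rose by 1.96 in wild type against 0.09 in rcf1-1, where its change was not called. Its 0 h level was higher in rcf1-1, though not called, so the changes start from different levels.

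The remaining lists gave no call between genotypes at any time. No listed splicing factor of the SR family was paired with a probe set by the annotation used (0 of 19), so they are not analysed here. The starch and soluble sugar gene APL3 differed by -0.18 ± 0.41, 0.59 ± 0.41 and 0.32 ± 0.41 at the 3 times. The salicylic acid and defence genes SAG101 and WRKY53 differed by 0.09 ± 0.18 and 0.3 ± 0.27 at 24 h. For APL3, SAG101 and WRKY53, 0 were called, also adjusted over the list alone. The 3 root markers had a median of -0.15 at 24 h (camera adjusted p = 0.621), with 0 called either way. GI differed by 0.34 ± 0.3 and LEA4-5 by 1.68 ± 0.72 between genotypes at 24 h, and neither was called over all probe sets. Each is the only paired gene of its list, and only LEA4-5 had an unadjusted p under 0.05.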

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

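The results given here are those in which the cold response differed between the genotypes by the direct test of that difference. The tests of the actin control, of the count without the 24 h replicate 2 arrays, and every value without those arrays or with a term for them were chosen after the results were seen. At 12 h, 20 probe sets differed in their response. The log2 differences were 4.75 for AT2G32020, 3.82 for AT2G41730, 3.58 for AT2G04050, 3.13 for AT5G15950 and 1.79 for AT4G22470. They were -2.98 for AT4G21870, -2.92 for AT4G01130, -2.52 for AT5G17460, -2.48 for AT5G44680 and -1.96 for AT1G64890. Of these 10 genes, AT5G15950 alone was called whichever array was left out. At 24 h, 251 probe sets differed, with 6.55 for AT2G41730, 6.49 for AT2G04050, 4.98 for AT2G32020, 4.61 for NDB4 and 4.49 for AT5G40690. The negative differences were -3.13 for BHLH101, -2.71 for AT2G03420, -2.53 for AT3G18600, -2.27 for AT1G79150 and -2.25 for AT5G19240. Without rcf1-1 0 h replicate 2, BHLH101 (adjusted p = 0.087), AT2G03420 (0.11), AT1G79150 (0.073) and AT5G19240 (0.16) lost their call. Without rcf1-1 0 h replicate 1, BHLH101 (0.061), AT2G03420 (0.12) and AT5G19240 (0.13) did. Without wild-type 0 h replicate 2, AT2G03420 (0.07) and AT5G19240 (0.1) did, and AT5G19240 also without wild-type 0 h replicate 1 (0.091). BHLH101 fell in rcf1-1 from 7.01 at 0 h to 2.74 at 24 h, and its level in wild type was 3.86 at 0 h and 2.71 at 24 h, so its value is the 0 h difference and no measure of its cold response.

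The ribosome biogenesis list differed in its response at 12 h (camera adjusted p = 3.42e-04) and at 24 h (1.48e-07). Between genotypes it was not called at 12 h (0.627), and the 12 h value comes mostly from its level at 0 h. Its higher 0 h level in rcf1-1 is part of the 24 h value too. At 24 h the COR genes (3.52e-04), the flavonoid and anthocyanin genes (0.0482, median -0.63 over 5 genes, with 0 called and 2 negative adjusted over the list alone) and the oxidative and mitochondrial stress genes (0.00185) differed too. With an estimated correlation none of these 5 list calls held. Their adjusted p was then 0.208, 0.054, 0.391, 0.489 and 0.0952.

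The first pattern weighed is the shift that the 24 h replicate 2 arrays of both genotypes share. Movement along the wild-type 12 h response is argued against, since the mean replicate difference at 24 h correlated with it at r = -0.11 across probe sets. The correlation with the wild-type 24 h response, which contains 1 of those arrays, was 0.27. A stage that departs from the 12 h response was not tested, so another stage of the cold response stays open. A narrower value distribution does not account for the shared shift, since r stayed at 0.66 after quantile normalization against 0.69 before. RNA with a 3' bias or weak labelling may be the source, since the actin 5' minus 3' difference was at most -5.89 on both arrays and at least -2.03 on the others. On both arrays the dap (3.16 and 3.95, others 6.07 to 7.54) and thr controls (3.52 and 3.59, others 4.96 to 6.46), made to be added to RNA before labelling, were lower and the bioB hybridization control higher (7.99 and 8.21, others 5.84 to 6.85), but the labels do not say how controls were added, so a difference in harvest or hybridization stays open.

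The second pattern is the rise of the genotype difference from 25 to 307 to 1706 called probe sets. This rise was not found with array quality weights (995, 2982 and 268) or with the compared arrays alone (331, 3874 and 17). In both, 24 h had the fewest calls. Both settings count the shared shift as 24 h spread, though much of it cancels between genotypes, so they cannot decide whether the difference grows. Whether the spread of the 24 h replicate 2 arrays makes the 24 h count stays open, since without them (4875 calls at 24 h, 3105 at 12 h) each 24 h group has 1 array, the error comes from the tighter 0 h and 12 h groups, and 62% of simulated calls at 24 h were false. The covariance between the genotype difference in replicate 1 and in replicate 2 was 4.33 times higher at 24 h than at 0 h, where unequal noise alone would leave it level. With the replicates crossed the covariance at 24 h was -0.0146, as the shared shift then enters with opposite signs, and the mean over both pairings gave a ratio of 1.98, under the bound of 2. The plain pairing was the one named in advance but was settled on after both had been computed, so a growing effect of rcf1-1 in the cold stays a hypothesis that rests on that choice at 24 h, while at 12 h the ratio was 2.22 plain and 2.16 over both pairings.

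For the difference averaged over the 3 times, 1 of 100 drawn splits within times, the real one, gave as many called probe sets. The real value was 1921 and the highest of the other splits 1649. That highest split kept the genotypes apart at 0 h and 12 h and parted the 24 h arrays by replicate number, which is the structure described above. The drawn splits that put replicate 1 of one genotype with replicate 2 of the other at 24 h gave 0 calls. As the splits thus differ in the spread they leave, the real split ranks first, but chance in how the arrays were grouped is not excluded.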

How the results depend on the processing

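The fits without both 24 h replicate 2 arrays and with a 24 h pair term (a term for those arrays) were chosen after seeing the data; the others were set in advance. No named gene call reversed under any of these settings. Without the trend, with the dim filter, with array quality weights and with the compared arrays alone the differences stay the same, so no direction could turn. For genes named because their arrays lie apart, leaving out a single array cannot turn the direction either. Array quality weights lost 35 of 263 named calls and the compared arrays alone 67 of 253, and each of these settings gained 9. Lists were tested with an estimated correlation, the replicate block, the mean over all probe sets and both added fits alone, where no list call reversed. Counts are given in the order rcf1-1 against wild type at 0 h, 12 h, 24 h and averaged, wild type at 12 h and 24 h, rcf1-1 at 12 h and 24 h, and the difference of responses at 12 h and 24 h; the reported ones were 25, 307, 1706, 1921, 2724, 2994, 2784, 4734, 20 and 251. With the replicate block they were 28, 304, 1736, 1941, 2812, 3203, 2890, 5088, 16 and 235. The numbers do not pair the samples by design; apart from the 24 h groups with each other, the deviations of the 14 other pairs of groups correlated at -0.1 to 0.09. Without both 24 h replicate 2 arrays the counts were 1216, 3105, 4875, 6156, 6498, 5612, 6713, 7724, 682 and 3150. With the 24 h pair term they were 691, 2196, 5426, 5705, 5595, 5495, 5735, 7248, 393 and 2581. All calls of the reported fit kept their direction without those arrays. In contrasts without 24 h groups the differences are the same in both fits, so no direction could turn there. In the others the fit uses a part of the same arrays, so the kept direction is no separate evidence. In simulations 62% of the calls for the genotypes at 24 h were false without those arrays, and 40.5% with the 24 h pair term. The trend left out moved the 12 h genotype count to 478 and the 24 h difference of responses to 467. Array quality weights gave 995, 2982 and 268 for the genotypes at 0 h, 12 h and 24 h. They gave 5232 for wild type and 8043 for rcf1-1 at 12 h, and 584 and 147 for the differences of responses. The 24 h arrays had weights of 0.303 to 0.305, equal for both replicates of a group, so the weights cannot single out replicate 2. The arrays of the compared groups alone gave 331, 3874, 17, 5003, 785, 8550, 2001, 685 and 28 for all contrasts but the averaged one. In these fits the spread comes from the compared arrays alone, and it is widest at 24 h. A minimum of 2-fold left 349 for the averaged contrast, 231 higher and 118 lower. The side with more calls turned in at least 1 setting in 8 of the 10 contrasts, all but rcf1-1 against wild type at 0 h and rcf1-1 at 24 h. For the other moved counts the cause was not tested. The dim filter and the second quantile normalization kept every count within 1.5 times; the latter moved the positive share of the 12 h difference of responses from 55% to 68.8%. Leaving out 1 array, where the lone array of a group is assumed to vary like the others, gave 2 to 18, 23 to 40, 1768 to 2917, 804 to 3249, 1267 to 1620, 1415 to 5575, 1335 to 1430, 2078 to 6828, 4 to 9 and 37 to 964. Of 263 named calls, 172 held whichever array was left out, and 91 did not. With a single 24 h array left out, the shift shared by both replicate 2 arrays no longer cancels between genotypes. At an adjusted p under 0.01 the shared risers and fallers were 4 and 0 for 0 h with 12 h. They were 4 and 0 for 0 h with 24 h, and 38 and 9 for 12 h with 24 h. For the cold response they were 568 and 430 at 12 h, and 360 and 583 at 24 h. Of 90 tests of the fixed lists, 32 were called, and 6 with an estimated correlation; the replicate block gave 35, the mean over all probe sets 32, and the 2 added fits 39 each.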

Other observations

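The lists drawn from the annotation, all chosen after seeing the data, and the correlation tested below, whose prediction was also written after related values were seen, gave these values. In wild type at 24 h of cold, 9 of 18 nuclear-encoded photosynthesis genes fell, with NdhS at -1.68 ± 0.22 and PSB27 at -1.58 ± 0.33 (list median -0.71; camera adjusted p = 1.43e-06, and 0.0261 with an estimated correlation). This is the single call of these lists that held with an estimated correlation. The list was also called between genotypes at 0 h (median -0.22; 2.76e-05, and 0.053 with an estimated correlation), at 12 h (0.00195, and 0.128) and averaged (6.84e-04, and 0.107). It was called in wild type at 12 h (0.0199, and 0.272) and in rcf1-1 at 12 h (0.029, and 0.41) and 24 h (0.00473, and 0.168). PSB27 was at -1.02 without 24 h replicate 2, and lost its own call without 0 h replicate 1 (adjusted p = 0.074) or replicate 2 (0.053). Of 12 nuclear RNA polymerase subunit genes, 6 rose in wild type at 24 h, among them NRPA1 by 1.42 ± 0.22 (adjusted p = 3.43e-04, and 0.431 with an estimated correlation). Between genotypes at 24 h, NRPA1 was at -1.11 ± 0.22 and NRPA2 at -1.33 ± 0.32, while the list was not called (0.459). It was called between genotypes at 0 h (7.88e-07, and 0.0977 with an estimated correlation) and for the difference of responses at 24 h (5.47e-04, and 0.439). At 24 h 3 of 10 autophagy genes were higher in rcf1-1, with ATG8E at 3.04 ± 0.28, ATG8H at 1.22 ± 0.21 and ATG8G at 0.89 ± 0.23 (adjusted p = 3.96e-05, and 0.462 with an estimated correlation). At 0 h the 21 RNA splicing and export genes had a median of 0.33 with 0 called (adjusted p = 4.29e-05, and 0.0977 with an estimated correlation). For the difference of responses this list had medians of -0.31 at 12 h (0.0424, and 0.745) and -0.34 at 24 h (0.0261, and 0.439). The autophagy list was also called averaged over the times (6.84e-04, and 0.334) and for the difference of responses at 24 h (0.00414, and 0.439).

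Among 11 tau glutathione transferase genes, GSTU22 was higher in rcf1-1 at 24 h by 3.42 ± 0.24 and GSTU25 by 1.98 ± 0.45, while the list itself gave an adjusted p of 0.281. Of 48 UDP-glycosyltransferase genes 3 were higher, led by UGT73C1 at 4.43 ± 0.44, and 2 lower (0.281). The 14 ER protein folding genes included BZIP60 at 3.19 ± 0.21, with 2 higher and 1 lower (0.587). Of 27 cell wall loosening genes 1 was higher and 3 lower, with XTH16 at -1.55 ± 0.32 (0.383). SWEET11 was the only called member of 14 SWEET sugar transporters, at -0.84 ± 0.2 (0.979). Without wild-type replicate 1, NRPA2 (adjusted p = 0.087), ATG8G (0.12) and SWEET11 (0.075) lost their call. Without rcf1-1 replicate 1, these and GSTU25 (0.092) did, and GSTU25 also without wild-type replicate 2 (0.087). ATG8G (0.074) lost it without rcf1-1 replicate 2. In the 24 h genotype contrast 0 genes were called among 69 chloroplast-encoded genes (0.944), 15 mitochondria-encoded genes (0.698), 13 tetrapyrrole synthesis genes (0.504), 8 TCA cycle genes (0.459), 7 calmodulin-like protein genes (0.0634), 9 U-box ubiquitin ligase genes (0.281) and 13 cell division and histone genes (0.979). In other contrasts, the tau glutathione transferase list was called for the difference of responses at 12 h (0.0244, and 0.45 with an estimated correlation) and 24 h (0.0315, and 0.439). The cell wall loosening list was called between genotypes at 0 h (0.007, and 0.0977) and for the difference of responses at 12 h (0.0244, and 0.363). The chloroplast-encoded list was called in rcf1-1 at 12 h (0.0175, and 0.661) and for the difference of responses at 12 h (0.00981, and 0.754). The UDP-glycosyltransferase list was called at 12 h in wild type (0.0207, and 0.726) and rcf1-1 (0.0495, and 0.661), and the calmodulin-like list averaged over the times (0.0243, and 0.334).

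The rcf1-1 arrays at 24 h scored further along the cold component than wild type, which led to the hypothesis that rcf1-1 moves further along the wild-type cold response. The genotype difference at 24 h correlated with the wild-type 12 h change, with which it shares no array, at r = 0.22 across probe sets, just above the bound of 0.2 set for it. Without the 24 h replicate 2 arrays r was 0.2, which does not exceed that bound. The genotype difference at 12 h correlated with the wild-type 24 h change at 0.01. The share of the 24 h difference that lies along the cold response was not measured, and the hypothesis stays open.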
